A study of Mus musculus with 16 samples.

How the data were processed

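RNA-seq was run on 16 libraries from dorsal root ganglia of naive mice aged 8 to 12 weeks. Per the labels, the mice carried Nav1.8-Cre and the Rosa26fsTRAP allele on a C57BL/6J background, so that an EGFP-L10a fusion is made in Nav1.8-expressing neurons. Per the series design text, ganglia of 3 mice of one sex were pooled for each of 4 replicates per sex, 24 mice in all, and each pool gave a total RNA library (IN) and a library of RNA from the pulldown of the tagged ribosomes (IP). Per the labels' protocols, RNA was eluted with the Direct-zol kit and libraries were made with ribosomal RNA depletion (Illumina total RNA Gold).

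Per the submitters' processing notes, FastQC, STAR 2.2.1 and StringTie 1.3.5 and the genome build GRCm38.p5 were used. The annotation release and the strand setting are not given in the sources used here. The deposited values were read as TPM per gene as the authors computed them, because the column, with genes, pseudogenes, noncoding RNA and ERCC spike-in entries, sums to 1000000 in each library. The header line ends in Coverage, so the unit rests on that sum and on the order of the columns. TPM are corrected for gene length and for the total of a library, but not for what that total is made of, and they keep no read counts, so the depth per sample is unknown and no interval that needs it was computed. A few RNA species held most of the total in IN and less of it in IP, so that TPM of the 2 fractions are not on the same scale. Tests made for read counts were not used.

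Entries of the same gene ID were summed (17 to 21 entries per library), which left 53379 gene IDs besides 92 ERCC entries. ERCC entries were left out of the tests because the amount added to each library is not given in the sources used here. Gene types came from GENCODE M21 (GRCm38), which held 53274 of the IDs, 21852 of them nuclear protein-coding genes. Coordinates are those of the deposited files. No pair of libraries held identical values (0 pairs). Correlations across genes within a group, for log2 values, were between 0.963 and 0.987, and genes are not independent replicates.

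TPM were scaled between libraries by the median of ratios to the geometric mean over the tested genes (factors 0.375 to 0.532 for IN and 1.65 to 2.69 for IP), and log2 was taken after adding 1. A gene was tested where its mean deposited TPM was at least 1 over the 8 IN or over the 8 IP libraries. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This is limma's moderated test, which shares the variance across genes. There were 6 comparisons: IP against IN in both sexes and in each sex, with the pool as a block, female against male in IN and in IP, without a block, and the interaction of sex and fraction, as female minus male, with the pool as a block. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for reading and figures.

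The IN and IP libraries of a pool are paired by the series design text. As a check, the correlation across genes of the deviations from the group mean was computed for the IN and IP library of the same number. It was 0.014, 0.116, 0.198 and 0.414 in female pools and 0.007, 0.276, 0.208 and 0.323 in male pools, and in 3 pools of each sex no other IP library of that sex had a higher value.

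Gene lists (40) for cell types, channels, receptors and pathways were fixed before the data were examined, as were the comparisons, the filter, the rule for named genes and the alternatives not said to be added later. Of 757 symbols listed 752 were matched, 4 of them by a synonym. Lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and also with an estimated correlation and with fry, which tests whether the genes of a list move one way and does not compare them with other genes. In IP against IN in both sexes 22 of 39 lists passed in camera, 5 up and 17 down, 0 with an estimated correlation, and 37 in fry. For female against male in IN the numbers were 13, 1 and 2, in IP 18, 1 and 1, and for the interaction 12, 0 and 1.

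Genes were named by a fixed rule. Per comparison these were the 10 largest positive and the 10 largest negative log2 changes among genes past 0.05 with a proper symbol (no Gm number, Rik clone, Ensembl ID or pseudogene) and with the same sign in every pool, or with no overlap between groups. Where fewer than 10 genes passed, the 10 with the smallest p were added as not passing. Up to 4 members of each list, those with the largest and smallest change, any member of the prostaglandin, X-linked escape and Y-linked lists, and Scn10a completed the rule. Not every gene it allows is named, and some results are not reported here.

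The model fit was tested on simulated log2 values with the spread of the real libraries, in which 200 of 16099 genes were changed by known amounts. Genes were drawn independently, with the same spread in every library and no differences between pools. Scaling and the filter were not simulated, and far fewer genes were changed than passed in the real IP against IN. The rates hold for those conditions only. Of genes changed by a log2 of 0.5, 1 and 2, the fit for IP against IN recovered 85.1%, 100% and 100%, with 9 false calls. Female against male in IN gave 68.7%, 94.0% and 100% (12 false calls), female against male in IP 37.3%, 85.1% and 100% (6), and the interaction 23.9%, 82.1% and 98.5% (7).

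The alternatives were a pseudocount of 0.1, no filter, a filter at 5 TPM, deposited TPM without scaling, quantile normalization, protein-coding genes only, limma's arrayWeights, robust eBayes, no block, the replicate number as a block, a fold of at least 1.5 with a standardized mean difference of at least 2 in place of the adjusted p, and leaving out each pool in turn. Without scaling, single genes were read relative to the median gene. After the data were seen, the mean level of mitochondrially encoded genes was added as a covariate for female against male in IP. Reads, splicing and isoforms were not analysed here.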

Results

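Total RNA of whole dorsal root ganglia (IN) and RNA bound to tagged ribosomes of Nav1.8-expressing neurons (IP) were profiled by RNA-seq in female and male mice. The mice carried Cre recombinase under the promoter of Scn10a, the gene of the sodium channel Nav1.8 of pain-sensing neurons (nociceptors). They also carried a Cre-dependent fusion of EGFP and the ribosomal protein L10a, so that pulling down the fusion brings along ribosomes of these neurons with their RNA, a method known as translating ribosome affinity purification. Each pool held ganglia of 3 mice and gave 1 IN and 1 IP library. With 4 pools per sex there were 16 libraries in 4 groups of 4. The values were TPM, transcript abundances scaled to a constant total per library, which keep no read depth, so the depth behind each value is unknown. Nuclear protein-coding genes held 9.58% to 13.3% of the TPM in the IN libraries and 44.9% to 79.5% in the IP libraries. The 8 most abundant entries, which were 2 genes of 7SL RNA, 4 short entries that overlap them, a short entry on chromosome 6 and the mitochondrial ribosomal RNA mt-Rnr2, held 70.05% to 78.0% in IN and 9.19% to 41.7% in IP. The IP library of female pool 2 had the lowest protein-coding share of the IP libraries, and that of female pool 4 the next lowest (57.6%). Between 12737 and 13846 genes reached 1 TPM in an IN library, and between 15377 and 16050 in an IP library. Values below are scaled TPM with the SD over libraries, and log2 changes of the scaled TPM with 1 added are given with the standard error (SE) of the fit. Counts of list members are over all tested genes, and the same counts adjusted over the list alone did not differ unless given.

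The comparison of IP with IN asked which transcripts were enriched on ribosomes of Nav1.8 neurons. Scn10a (ENSMUSG00000034533.10, chromosome 9, 119608456 to 119719322, GRCm38) was at 381 ± 46.8 in IP and 125 ± 12.4 in IN (SD, n = 8 each), a 3.03-fold rise (log2 1.60 ± 0.08, limma adjusted p = 7e-08) seen in 8 of 8 pools. Of the 32 nociceptor genes tested, 30 rose and 1 fell. Nppb, a peptide of itch neurons, rose by a log2 of 1.98 ± 0.10, while the adrenergic receptor gene Adra2a fell by 0.74 on that scale. The list median was a log2 of 1.33, with a camera adjusted p of 3e-09 against all other genes, and adjusted p = 0.40 with an estimated correlation. In the IP of female pool 2 the median was 0.96, and in the other pools it was 1.33 to 1.49. Among the 17 tested genes of the neuropeptide list 15 rose and 2 fell (median log2 1.05, adjusted p = 0.00032, adjusted p = 0.40 with an estimated correlation). The list was fixed with some genes that encode no neuropeptide, such as Sncg and Pcsk1. It shares Nppb, Calca, Calcb, Tac1 and Sst with the nociceptor list, so the results of these lists are not independent. Nmb, which encodes neuromedin B, rose from 54.1 ± 18.4 to 289 ± 100, and Penk, which encodes enkephalin precursors, fell from 4.41 ± 1.32 to 0.999 ± 0.38. With the deposited TPM and no scaling the call for this list was lost (adjusted p = 0.083).

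Markers of large-diameter neurons, which carry touch and muscle sense, went the other way. Of 16 tested, 15 fell and 0 rose (median log2 -1.26, adjusted p = 3.5e-05, adjusted p = 0.40 with an estimated correlation). Spp1, an osteopontin gene active in muscle-sense neurons, fell from 92.7 ± 8.6 to 9.51 ± 4.82. Pvalb, the gene of the calcium-binding protein parvalbumin, fell from 60.5 ± 12.8 to 8.58 ± 6.85, and it also stands on the list of skeletal muscle genes. For genes of unmyelinated touch neurons (C-LTMR) 5 of 8 rose and 2 fell (median 0.39, adjusted p = 0.15). Th, tyrosine hydroxylase of the dopamine pathway, rose by 1.20 ± 0.04, and the transcription factor gene Zfp521 fell by 0.35 on the log2 scale. Zfp521 did not move the same way in every pool, and its call was lost with deposited TPM (adjusted p = 0.12) and with quantile normalization (0.17). Pan-neuronal genes were split, with 10 of 17 higher and 3 lower (median 0.52, adjusted p = 0.076). Avil, an actin regulator of sensory neurons, rose by 1.35 and the ubiquitin hydrolase gene Uchl1 by 1.15, whereas Map2, a dendritic microtubule protein gene, fell by 1.46 and the neurofilament gene Nefm by 0.58, which was -0.14 relative to the median gene of the deposited TPM (adjusted p = 0.41). The largest other rises with the same sign in every pool included Kcnk12 (2.04 ± 0.14), a potassium channel gene, and Nrn1l (2.01 ± 0.08). Dusp26 (1.97 ± 0.11), Tmem158 (1.92 ± 0.08), Cd55b (1.90 ± 0.12) and Tmem79 (1.89 ± 0.15) followed. Snurf had the largest value (4.31 ± 0.56), but it overlaps Snrpn, and its IN level was 164 and 122 in female pools 1 and 4 against 5.85 to 8.01 in the other pools. This value is therefore uncertain.

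Genes of glia and of other non-neuronal cells fell in IP. Of the satellite glia list, 14 of 15 fell and 0 rose (median log2 -2.68, adjusted p = 9.2e-06), and all 14 of the myelinating Schwann cell list fell (median -2.60, adjusted p = 4.6e-06). Ugt8a, an enzyme of myelin lipid synthesis, fell by 3.41 on the log2 scale and the fatty acid binding protein gene Fabp7 by 3.26. All 5 genes of a list fixed as astrocyte fell (median -2.25, adjusted p = 0.0047), which does not show that the ganglia held astrocytes. All 12 of the leptomeninges (-2.36, 7.2e-06), all 12 of fibroblasts (-2.39, 9.5e-06) and all 11 of macrophages (-2.23, 7.5e-06) fell. Examples were Gfap, an intermediate filament gene of glia, at -2.42, and Ogn at -3.86 and Igf2 at -3.21 for the leptomeninges. The matrix protein gene Dcn was at -3.22, the lysozyme gene Lyz2 at -3.09 and the complement gene C1qa at -2.47. All 4 genes of T, B and granulocyte cells (-2.89, adjusted p = 0.0054), all 6 mural (-1.57, 0.0056), all 6 erythrocyte (-3.05, 0.00098) and all 5 adipocyte genes (-1.59, 0.013) fell as well. Of the endothelial list 10 of 11 fell (-1.77, adjusted p = 0.00019), and of the perineurial list 6 fell and 1 rose (-1.80, adjusted p = 0.017). The calprotectin gene S100a9 fell by 3.29, the endothelial cadherin gene Cdh5 by 2.27, the haemoglobin gene Hbb-bs by 3.27 and the tight junction gene Cldn1 by 2.75. For each of these lists the adjusted p was 0.40 with an estimated correlation, and the adipocyte call was lost without the pool as a block (0.066). The 9 skeletal muscle genes all fell (median -2.16, adjusted p = 0.0048, adjusted p = 0.50 with an estimated correlation), among them the troponin gene Tnnt3 at -2.96 ± 0.34. The medians of skeletal muscle (-0.17), satellite glia (-1.66) and myelinating Schwann cells (-1.67) in female pool 2 were nearer to 0 than those in any other pool. Lists without a call were non-myelinating Schwann cells, with 3 of 7 higher and 3 lower (median -0.04, adjusted p = 0.88), and bone and cartilage, with 2 of 3 lower (-1.17, adjusted p = 0.23). Gfra3, a co-receptor of glial factors that nociceptors also express, rose by 1.28 and Sostdc1 fell by 2.71. The oligodendrocyte list had 2 tested members, 1 higher and 1 lower (median -0.29), too few for the list test.

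Ion channel and receptor genes moved both ways. For TRP, ASIC and Piezo channels, which gate responses to heat, acid and pressure, 14 of 23 rose and 5 fell (median log2 0.39, adjusted p = 0.017, adjusted p = 0.40 with an estimated correlation). P2rx3, a receptor of extracellular ATP, rose from 62.0 ± 3.09 to 229 ± 33, Trpa1, a receptor of irritants, rose by 1.37, and Trpm7 fell by 0.80. This call was lost with deposited TPM (adjusted p = 0.052) and with quantile normalization (0.056). Of the 14 sodium channel genes 6 rose and 7 fell (median -0.10, mean 0.19, adjusted p = 0.99). Scn11a, the gene of Nav1.9, rose by 1.84 and Scn1a fell by 1.29. Of 33 potassium channel genes 16 rose and 15 fell (median 0.08, mean -0.06, adjusted p = 0.91), with Kcnn1 at 1.15 and Kcnk1 at -1.69. Calcium channel genes gave 8 higher and 7 lower of 15 (median 0.26, adjusted p = 0.53), with Cacnb3 at 1.13 and Cacna1g at -1.46. Among opioid, cannabinoid and serotonin receptors 11 of 19 rose and 6 fell (0.31, adjusted p = 0.21). Oprm1, the mu opioid receptor gene, rose by 1.10, the serotonin-gated channel gene Htr3a rose 2.47-fold, and Htr1d fell by 1.59. Neurotrophic factor and cytokine receptors gave 14 higher and 11 lower of 29 (0.14, adjusted p = 0.64). Ret, a receptor of glial cell line derived factors, rose by 1.29 and Ntrk2, the receptor of brain-derived neurotrophic factor, fell by 2.62.

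Genes of prostaglandin synthesis and signalling, the pathway that the study's title names, also split in IP against IN. Of 22 tested, 9 rose and 10 fell (median log2 -0.11, adjusted p = 0.75). Receptor genes were among those higher, with Ptgir (prostacyclin receptor) at 25.2 ± 2.72 in IP against 10.5 ± 1.01 in IN, Ptger1 at 1.15 ± 0.06 on the log2 scale, Ptgdr at 0.99 ± 0.06 and Ptger3 at 0.82 ± 0.05. The carbonyl reductase gene Cbr1 rose by 1.04 and the phospholipase gene Pla2g6 by 0.47. The prostaglandin D2 synthase gene Ptgds (ENSMUSG00000015090.13, chromosome 2, 25466709 to 25470046) fell from 402 ± 140 to 42.2 ± 41.9, or by 3.49 ± 0.20 on the log2 scale. The cyclooxygenase gene Ptgs1 fell by 2.04, the synthase gene Ptges by 1.58 and the degrading enzyme gene Hpgd by 1.63. Receptor genes Ptgfr at -1.92 and Tbxa2r at -1.13, and the receptor regulator Ptgfrn at -1.49, were lower too.

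Transcripts of the mitochondrial genome and several noncoding RNAs had the largest falls. All 15 mitochondrially encoded genes fell (median log2 -5.23, adjusted p = 9.5e-06, adjusted p = 0.40 with an estimated correlation). The ATP synthase gene mt-Atp6 went from 705 ± 150 to 18.4 ± 26, mt-Co2 fell by 5.97 ± 0.65 and mt-Nd6 by 4.19 ± 0.20. The pool medians ran from -2.87 in female pool 2 to -7.10 in male pool 4. Nuclear genes of oxidative phosphorylation rose instead, 35 of 38 with 0 lower (median 0.50, adjusted p = 4.6e-06, adjusted p = 0.40 with an estimated correlation). Cox6c rose by 0.89 ± 0.14 and Ndufa4, another part of the respiratory chain, by 0.86 ± 0.08. Of 78 cytosolic ribosomal protein genes 58 rose and 1 fell (median 0.32, adjusted p = 4.6e-06, adjusted p = 0.40 with an estimated correlation). With quantile normalization both calls were lost, at adjusted p = 0.16 for oxidative phosphorylation and 0.93 for ribosomal proteins, whose median was then 0.06. Rpl10a rose by 1.36 ± 0.06, but the transgene carries Rpl10a sequence, so its reads cannot be assigned to the endogenous gene alone. Rplp0, a protein of the ribosomal stalk, fell by 0.42 ± 0.06, and relative to the median gene of the deposited TPM its value was 0.01. Nuclear long noncoding RNAs gave 1 higher and 10 lower of 14, and 1 higher and 11 lower adjusted over the list alone (median -1.99, adjusted p = 0.0056, adjusted p = 0.41 with an estimated correlation). Malat1 fell from 1998 ± 359 to 186 ± 181 and Meg3 by 2.91. All 6 tested members of a list fixed as cytoplasmic noncoding RNA, which also holds mainly nuclear RNAs such as Rn7sk and nucleolar ones such as Rmrp, fell (median -4.00, adjusted p = 0.0048, adjusted p = 0.40 with an estimated correlation), Rny1, a small RNA bound by the Ro protein, from 357 ± 60.1 to 14.6 ± 15.1.

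The remaining lists had no call. Translation control genes gave 18 higher and 13 lower of 40, and 17 and 13 adjusted over the list alone (median log2 0.12, adjusted p = 0.59). The initiation helicase gene Eif4a1 rose by 0.82 and the kinase gene Rps6ka1 fell by 1.03. Immediate early and injury genes gave 3 higher and 7 lower of 15, and 3 and 6 adjusted over the list alone (-0.06, adjusted p = 0.42), with Nr4a1, an activity-induced receptor gene, at -2.06. Interferon response genes gave 7 higher and 12 lower of 28 (-0.10, adjusted p = 0.43), from Ifi27 at 1.02 to Isg15 at -1.58. Sex hormone signalling gave 5 higher and 6 lower of 14 (-0.02, adjusted p = 0.68), with the oestrogen receptor gene Esr1 at -1.03. Replication-dependent histones gave 7 higher and 6 lower of 15 (0.09, adjusted p = 0.68). Of the X-linked escape genes 1 rose and 5 fell of 11, and 0 and 5 adjusted over the list alone (-0.34, adjusted p = 0.37). Of the 4 Y-linked genes 3 fell (-0.43, adjusted p = 0.39). That value includes the female pools, where these genes were near 0 in both fractions. The list median was -0.01 to 0 in female pools and -1.05 to -0.72 in male pools.

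**Figure D1:**
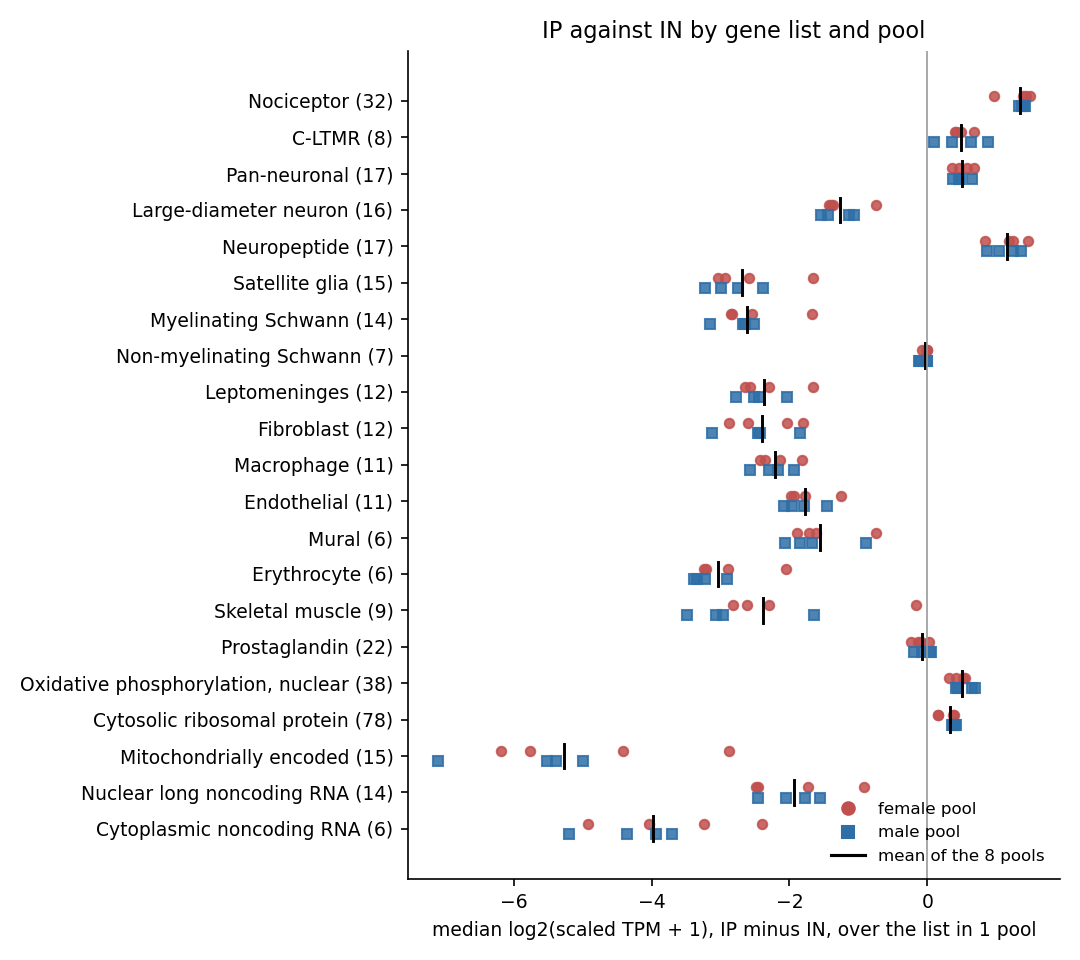
Median log2 change of IP minus IN (scaled TPM with 1 added, horizontal axis) over the members of each gene list within 1 pool, with the number of members in brackets; circles are female pools, squares male pools, and the black line is the mean of the 8 pools. Nociceptor genes lie above 0 in every pool (0.96 to 1.49) and myelinating Schwann cell genes below 0 in every pool (-1.67 to -3.15), with female pool 2 nearest to 0 in both.

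Over all 16099 genes tested, 12783 passed an adjusted p of 0.05 in limma's moderated test with the pool as a block, 6514 higher and 6269 lower in IP. A change of 2-fold or more was seen for 2600 of them, 501 higher and 2099 lower. The change from IN to IP had the same sign in all 8 pools for 66.2% of genes, where chance gives 0.78%. Directions are relative to the median gene, because the deposited TPM were higher in IP by a median log2 of 1.84. Without scaling 94.0% of the 15558 genes past the threshold were higher in IP, and with quantile normalization, which shifted the median by 0.151, 61.1% of 12979 were, against 51.0% in the scaled data. The balance turned the other way without the low-value filter, where 35913 genes were tested and 32.8% of the 21019 past the threshold were higher.

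IP and IN were also compared within each sex. Scn10a rose by 1.51 ± 0.14 in female pools (131 ± 11.5 to 381 ± 69.6, SD, n = 4, limma adjusted p = 0.00053) and by 1.68 ± 0.08 in male pools (118 ± 10.4 to 380 ± 15.9, adjusted p = 2e-05). Nmb rose by 2.08 ± 0.32 and 2.65 ± 0.15, and mt-Atp6 was at -5.72 ± 0.98 and -7.40 ± 0.77. Without 1 pool mt-Atp6 ran from -6.65 to -4.50 in females and from -8.10 to -6.65 in males. Its IP level was 0.0531 in female pool 3, 0.067 in male pool 3 and 0.0501 in male pool 4, against 11.5 to 78.3 in the other pools. Ptgds was at -3.23 ± 0.28 in female and -3.75 ± 0.20 in male pools. Female pools gave 10613 of 16093 genes past the threshold (5241 higher, 5372 lower), and male pools 11335 of 16094 (5675 higher, 5660 lower). Of 16088 genes tested in both, 4808 were called higher in both sexes, where 1848 would be if the calls were independent, and 5062 lower, where 1890 would be. Calls in opposite directions were made for 2 genes. The change had the same sign in all 4 pools for 74.1% of genes in females and 75.9% in males, where chance gives 12.5%. The deposited TPM shifted the median by 1.73 in females and 1.94 in males, with 95.3% and 94.5% of the genes past the threshold higher. Quantile normalization shifted it by 0.143 and 0.156, with 60.8% and 61.1% higher, against 49.4% and 50.1% in the scaled data. Without the low-value filter 32.5% of 15615 genes past the threshold in females and 32.8% of 17144 in males were higher. In each sex 22 of 39 lists passed in camera, 5 up and 17 down, and 0 with an estimated correlation (lowest adjusted p = 0.53 in females and 0.17 in males).

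The female and male IN libraries were compared to see how the total RNA of the ganglion differs by sex. Genes of the sex chromosomes had the largest differences. Xist, the RNA that silences an X chromosome (ENSMUSG00000086503.3, chromosome X, 103460375 to 103483217), was at 8.53 ± 1.99 in female and 0.012 ± 0.00998 in male IN (SD, n = 4 each, log2 3.21 ± 0.14, limma adjusted p = 1.4e-05). The Y-linked translation factor gene Eif2s3y was at 14.4 ± 0.943 in male IN and listed at 0 in every female IN library. Ddx3y, a Y-linked RNA helicase gene, was at 20.6 ± 1.48 in male IN and at 0 in the female libraries except 0.0438 in pool 1. The Y-linked demethylase genes Uty and Kdm5d were at -3.55 and -2.61 on the log2 scale. Eif2s3x, the X-linked partner of Eif2s3y, was higher in females, 32.9 ± 1.61 against 20.9 ± 1.21 (0.63 ± 0.06, adjusted p = 0.0057). With the replicate number as a block (adjusted p = 0.089) and with deposited TPM relative to the median gene (0.21), the Eif2s3x call was lost.

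Autosomal genes lower in female IN were Srd5a2, Rnasek, Commd1 and Ep400. Srd5a2, a 5-alpha-reductase that makes dihydrotestosterone (ENSMUSG00000038541.7, chromosome 17, 74017706 to 74047916), was at 0.091 ± 0.105 in female and 2.09 ± 0.603 in male IN (log2 -1.49 ± 0.14, adjusted p = 0.0057). Ep400, a chromatin remodelling ATPase (ENSMUSG00000029505.17, chromosome 5, 110664373 to 110770717), was at 13.6 ± 0.572 and 20.1 ± 1.15 (-0.53 ± 0.06, adjusted p = 0.017). Rnasek was at 11.3 ± 1.71 and 22.4 ± 1.92, and Commd1 at 5.64 ± 1.02 and 11.2 ± 0.393, but both overlap other annotated entries that can take their reads. Ep400 missed the threshold in each fit that left out 1 library except that without male pool 1, with adjusted p between 0.057 and 0.079, Rnasek in those without female pools 2 or 4 or male pools 1, 3 or 4 (0.075 to 0.10), and Commd1 in those without female pools 2 or 4 or any male pool (0.067 to 0.10). With the replicate number as a block each of these 3 was at 0.33, and relative to the median gene of the deposited TPM they were at 0.82, 0.21 and 0.13. Adjusted over autosomal genes alone, 1 autosomal gene passed, Srd5a2. Of the 11 X-linked escape genes 2 passed, and 7 adjusted over the list alone (median 0.27, adjusted p = 3.4e-13, adjusted p = 0.10 with an estimated correlation). All 4 Y-linked genes were lower in females (median -3.75, adjusted p = 1e-41, adjusted p = 0.00033 with an estimated correlation). The leptomeninges list was higher in female IN as a group (median 0.29, adjusted p = 1.2e-07, adjusted p = 0.41 with an estimated correlation), with 0 of 12 members passing and 1 higher adjusted over the list alone. Myelinating Schwann cell genes were lower (median -0.22, adjusted p = 1.2e-07, adjusted p = 0.41 with an estimated correlation), with 0 of 14 passing. None of the 22 prostaglandin genes passed, nor did any adjusted over the list alone, and Ptgds was at 472 ± 131 in female and 332 ± 125 in male IN (0.57 ± 0.32, adjusted p = 0.96), a difference of 0.24 without male pool 2 and 0.39 without female pool 2, and of 0.56 to 0.75 without any other pool. Scn10a was at 131 ± 11.5 and 118 ± 10.4 (0.15, adjusted p = 0.96).

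Of 16092 genes tested, 13 passed, 4 higher and 9 lower in female IN, and 774 had an unadjusted p under 0.05, where chance gives 805. The 3 genes not yet named were chosen after their values were seen: Gm29650 on the Y chromosome, Gm27927 within the Xist locus, and the X-linked pseudogene Gm2223, at 27.6 in female and 16.2 in male IN. Gm2223 missed the threshold without any 1 of female pools 1 to 3 or male pools 1 to 3 (adjusted p between 0.054 and 0.11). The groups did not overlap for 2.83% of genes, where chance gives 2.86%.

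The female and male IP libraries were compared to find transcripts that differ by sex on ribosomes of Nav1.8 neurons, the question of the study's title. Again the Y-linked genes differed most. Eif2s3y was at 12.2 ± 1.25 in male IP and listed at 0 in every female IP library, and Ddx3y was at 12.1 ± 1.7 in male IP and at 0 in the female libraries except 0.00257 in pool 4. Uty was at -2.47 ± 0.11 and Kdm5d at -1.65 ± 0.08 on the log2 scale. Eif2s3x was at 34.1 ± 3.14 in female and 21.3 ± 0.718 in male IP (SD, n = 4 each, log2 0.65 ± 0.08, limma adjusted p = 0.042). It missed the threshold in each fit that left out 1 library except that without female pool 4, with adjusted p between 0.12 and 0.27, with the replicate number as a block it was at 0.84, and with quantile normalization at 0.058. Xist did not pass, at 3.56 ± 5.46 against 0.00173 in male IP (1.56, adjusted p = 1), and its female values were 1.09, 11.7, 0.814 and 0.591, the highest in pool 2. Scn10a was at 381 ± 69.6 and 380 ± 15.9 (-0.02, adjusted p = 1).

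Of the 22 prostaglandin genes 0 passed in IP, and 0 adjusted over the list alone (median log2 -0.01, mean 0.06, adjusted p = 0.89). Ptgds was at 61.5 ± 55.2 in female and 22.9 ± 7.19 in male IP (1.09 ± 0.48, adjusted p = 1). Its values were 25.7, 144, 33.1 and 43.7 in female pools and 28.2, 17.8, 29.9 and 15.7 in male pools, and without female pool 2 the difference was 0.58 ± 0.26. Among the 10 genes with the smallest p that did not pass were Srd5a2 (0.0288 in female and 1.02 in male IP, -0.95, adjusted p = 0.18), the ribosome assembly gene Gtpbp4 (3.76 ± 0.526 and 8.76 ± 2.4, -1.01, adjusted p = 0.67) and the injury-induced transcription factor gene Atf3 (1.49 ± 0.112 and 3.24 ± 1.11, -0.73, adjusted p = 1). Ep400 was at 10.5 ± 1.27 in female and 7.49 ± 0.264 in male IP (0.43 ± 0.09, adjusted p = 1). The others were Map3k1 (0.48), Pcdha8 (0.43), Gm6222 (-0.37), Dopey2 (0.34), Lime1 (0.53) and Zmym1 (0.63), each with an adjusted p of 1. Srd5a2 passed with a pseudocount of 0.1 (adjusted p = 0.042), with deposited TPM relative to the median gene (0.0011), with quantile normalization (0.011) and over protein-coding genes alone (0.04), and Gtpbp4 passed without male pool 2 (-1.19, adjusted p = 0.019).

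Several gene lists differed as groups between female and male IP. All 4 Y-linked genes were lower in females (median log2 -3.08, adjusted p = 4.1e-45, adjusted p = 0.0059 with an estimated correlation). X-linked escape genes were higher (median 0.30, adjusted p = 3.9e-07, adjusted p = 0.27 with an estimated correlation), with 1 of 11 passing. Lists of the leptomeninges (0.42, adjusted p = 4.5e-06), fibroblasts (0.34, 0.0032), erythrocytes (0.53, 0.00065) and mitochondrially encoded genes (0.92, 0.00012) were higher in female IP, and neuropeptides were lower (-0.13, 0.00037), with 0 members passing in any of the 5. With an estimated correlation each of these 5 had adjusted p = 0.72, and in fry 0.82. Without female pool 2, whose IP library was nearest to IN, the fibroblast list was at 0.04 (adjusted p = 0.095) and the mitochondrially encoded list at 0.31 (0.095). The IP library of female pool 4 also held much mitochondrial RNA, 4.84% of its TPM. This share was 5.04% in female pool 2 and 0.24% to 1.39% in the other IP libraries. The leptomeninges (0.17, adjusted p = 0.01), erythrocyte (0.25, 0.049) and X-linked escape (0.14, 3.9e-07) lists passed without it at lower medians. Without male pool 4 the fibroblast list was at 0.25 (adjusted p = 0.21) and the mitochondrially encoded list at 0.38 (0.19), and without female pool 4 the neuropeptides were at -0.16 (0.057).

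In IP, 8 of 16096 genes passed, 3 higher and 5 lower in females, and 362 had an unadjusted p under 0.05, where chance gives 805. The 3 not yet named were chosen after their values were seen: Gm527 (7.34 ± 0.394 in female and 3.73 ± 0.436 in male IP), Gm2223 and Gm29650. Gm527 missed the threshold without any 1 library except that of male pool 2 (adjusted p between 0.05 and 0.13), and Gm2223 without any except those of female pool 4 and male pool 2 (0.05 to 0.18). Adjusted over autosomal genes alone, 0 autosomal genes passed. The count was 5 without female pool 2, male pool 1 or male pool 4, and 12 without female pool 4. With the replicate number as a block it was 5. Deposited TPM shifted the median by -0.111 and gave 8 genes, 1 higher and 7 lower, and quantile normalization gave 2 higher and 6 lower. The groups did not overlap for 1.66% of genes, where chance gives 2.86%.

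**Figure D2:**
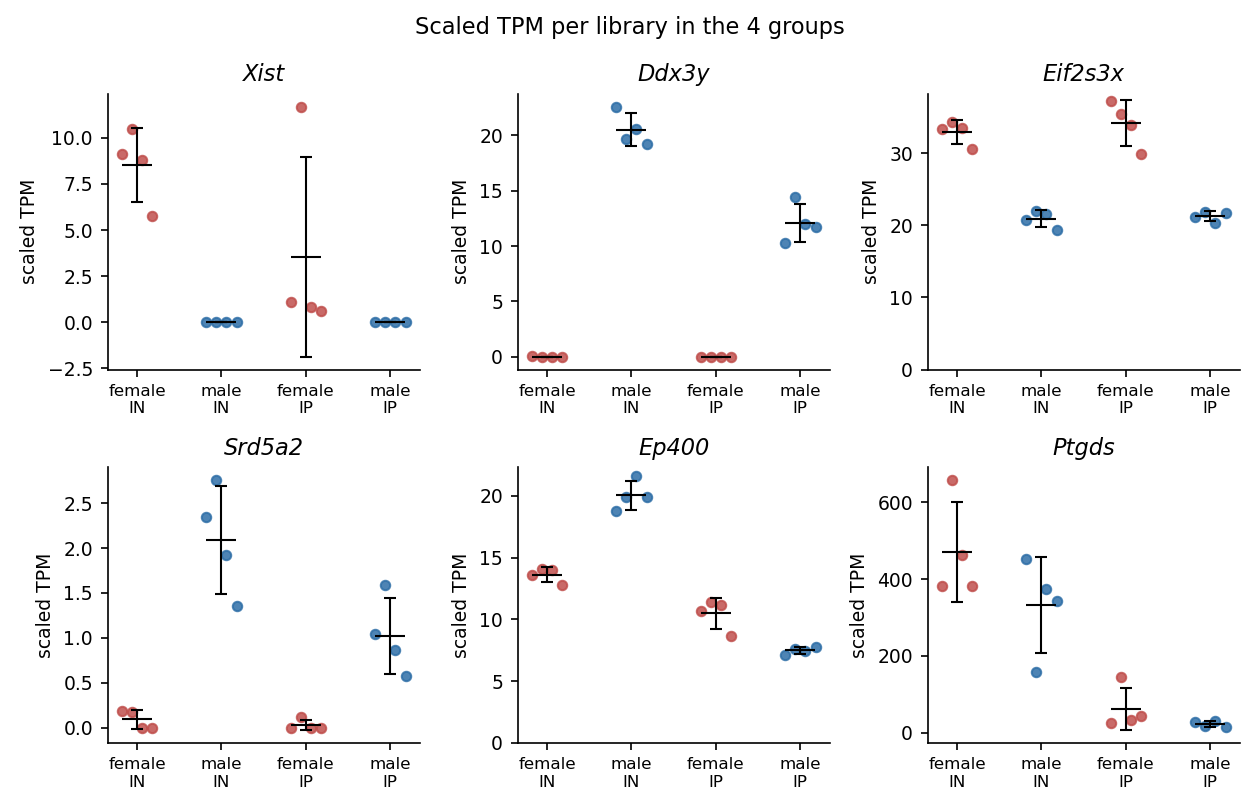
Scaled TPM (vertical axis) of 6 genes in each library of the 4 groups; points are libraries, red for female and blue for male, and black bars show the mean ± SD over 4 libraries. Ep400 is lower in female than in male IN (13.6 against 20.1) and higher in female than in male IP (10.5 against 7.49), and the highest Xist and Ptgds values in female IP (11.7 and 144) both belong to pool 2.

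The change from IN to IP was tested for a difference between the sexes, as an interaction. IN holds RNA of all cells of the ganglion and IP that of Nav1.8 neurons, so the test cannot tell ribosome association from cell composition. Ep400 passed. Its level went from 13.6 ± 0.572 to 10.5 ± 1.27 in females and from 20.1 ± 1.15 to 7.49 ± 0.264 in males (SD, n = 4 each), a female minus male difference of 0.96 ± 0.09 on the log2 scale (limma adjusted p = 0.01). The Y-linked genes Uty (1.08 ± 0.10) and Kdm5d (0.96 ± 0.09) passed as well, but their female levels were near 0, and the values follow from a fall in males alone, from 10.8 to 4.59 for Uty and from 5.13 to 2.15 for Kdm5d. Ptgds was at 0.53 ± 0.39 (adjusted p = 1) and at 0.18 ± 0.31 without female pool 2, and Scn10a was at -0.17. None of the 22 prostaglandin genes passed, nor did any adjusted over the list alone (median -0.06, mean 0.01, adjusted p = 0.88). The 10 genes with the smallest p that did not pass had adjusted p between 0.10 and 1. They were Gm12728 (-2.86), Srp19 (-0.86), Srd5a2 (0.54), Gm27640 (2.22), Acvr2b (0.55), Ddx3y (0.71), Snora17 (0.60), Tbl3 (-0.76), Rab13 (0.47) and Gm4987 (-0.37). Gm12728 passed without male pool 2 (-2.46, adjusted p = 0.013), with a pseudocount of 0.1 (-4.28, 0.024) and over protein-coding genes alone (-3.85, 0.022), and Gm27640 without male pool 3 (2.62, 0.04). Relative to the median gene of the deposited TPM Gm12728 (-3.11, adjusted p = 3.5e-05), Gm27640 (2.27, 0.047) and, with the opposite sign, Ddx3y (-1.34, 0.004) passed. Ddx3y was near 0 in both female fractions, so its female change was near 0 under any scaling. Its sign here follows from the deposited TPM of male pools, which rose from IN to IP by a median log2 of 1.94. The Y-linked list was at 0.84 (adjusted p = 3.3e-15, adjusted p = 0.097 with an estimated correlation), with 2 of 4 passing and 3 adjusted over the list alone. The mitochondrially encoded list was at 0.92 (adjusted p = 2e-05, adjusted p = 1 with an estimated correlation) with 0 of 15 passing, at 0.29 (adjusted p = 0.16) without female pool 2 and at 0.52 (0.017) without male pool 4.

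In total 3 genes passed, all higher, and 448 had an unadjusted p under 0.05, where chance gives 805. The count was 0 without female pool 3 or male pool 1, 1 without male pool 3, 5 without female pool 1, female pool 4 or male pool 2, and 6 without female pool 2. Ep400 missed the threshold without female pool 3 (adjusted p = 0.08), male pool 1 (0.068), male pool 3 (0.053) or male pool 4 (0.052), with a difference of 0.92 to 1.01 in the 8 fits. Uty and Kdm5d missed it without female pool 3, male pool 1 or male pool 3 at the same adjusted p, with a pseudocount of 0.1 (0.62 for both), over protein-coding genes alone (0.12 and 0.13) and with quantile normalization (0.15 and 1). With deposited TPM, which shifted the median by -0.208, 11 genes passed, 2 higher and 9 lower, and with quantile normalization 1 passed. Relative to that shift Uty (-0.81), Kdm5d (-0.68) and the Y-linked list (-1.07) changed sign, and Ep400 was at 0.92 (adjusted p = 0.62). The turn of the Y-linked genes follows from female levels near 0 and the rise of the deposited TPM in male IP. The changes in female and male pools did not overlap for 1.59% of genes, where chance gives 2.86%.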

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

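The tests of RNA carried over in the IP of female pool 2, of Ptgds and of Ep400, and the splits for autosomal genes alone, were chosen only after the results were seen; the other counts over splits of the samples were chosen before.

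In the IP library of female pool 2 many transcripts of non-neuronal cells lay far from their values in the other 7 IP libraries and toward IN. The genes with such a gap were Ugt8a (19.1), Pvalb (24.9), Sostdc1 (2.50), Ogn (31.6), Lyz2 (14.2), Cdh5 (2.03), Dcn (77.5), Tnnt3 (36.9), Cldn1 (2.32), mt-Atp6 (78.3), mt-Co2 (264), Malat1 (594), Rny1 (48.0), Hpgd (0.557), Ptgs1 (2.08), Ptgfr (3.70) and Ptgds (144), in scaled TPM, and Tmem79 was low at 59.1. Over genes at least 4 times higher in this pool's IN than in the other female IP libraries, the library held a median of 19.9% of the IN excess (quartiles 15.4 and 27.0, 914 genes), and the highest of the other 7 libraries held 7.0%, which restates the nearness to IN, so carry-over of whole-ganglion RNA cannot be told apart from another cause of it. A carry-over of every RNA class in a single proportion is argued against, since nuclear long noncoding RNAs held 33.0% (lower quartile 30.4) and mitochondrially encoded RNAs 10.6% (upper quartile 11.5). Skeletal muscle genes at 87.6% and Xist at 113% stand outside it too, and a difference of the mice in this pool stays open, as untested.

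Ptgds was higher in female than in male IP by 1.09 ± 0.48 on the log2 scale (adjusted p = 1), and its value of 144 in female pool 2 stood apart from the other female IP libraries. The share of the IN excess for Ptgds in that library was 17.5%, between the 10th and 90th percentile of all such genes (11.8% and 37.8%), so whatever moved those genes toward IN, carry-over or another cause, could account for this value. In IN the difference was 0.57 ± 0.32, and 0.24 without male pool 2 to 0.75 without male pool 1. The IP library of female pool 4, where Ptgds was at 43.7, also had a low protein-coding share (57.6%) and a high mitochondrial share (4.84% of TPM). It held 4.6% of the IN excess, against 7.0% in male pool 2, where Ptgds was at 17.8. Leaving out female pool 2 alone keeps both libraries. Without female pool 2 the difference in IP was 0.58 ± 0.26, and the difference between the sexes in the change from IN to IP was 0.18 ± 0.31. With so few pools, that interval cannot tell a difference already present in the total RNA from a difference on the ribosomes of Nav1.8 neurons, and a sex difference in these neurons stays open. Ptgds changed by -3.49 on the log2 scale from IN to IP in the fit of both sexes. Genes of non-neuronal lists had similar falls, such as Dcn (-3.22), Hbb-bs (-3.27) and Ogn (-3.86), and some smaller ones, such as Cdh5 (-2.27). The change therefore gives no sign that the remaining IP signal of Ptgds came from these neurons, and its source was not tested.

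The change of Ep400 from IN to IP differed between the sexes by 0.96 ± 0.09, with lower values in female IN and higher values in female IP. Among annotated genes that overlap Ep400, the largest IN difference between the sexes was 0.888 TPM, against 6.44 for Ep400. Reads of such a gene that were counted for Ep400 would be missing from its own value. The overlapping genes are short RNAs, and TPM are corrected for length, so these values are not read amounts. The check therefore cannot decide whether such reads played a part. A single library is argued against as the source of the sex difference of Ep400, which was at least 0.92 without any 1 pool. The call was still lost without female pool 3, male pool 1, male pool 3 or male pool 4. Relative to the median gene of the deposited TPM it was 0.92 with adjusted p = 0.62, so the call depends on the scaling. Intron reads, isoforms and unannotated transcripts were not tested, chance was not excluded, and a biological difference between the sexes may remain as a hypothesis.

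Besides Ep400, the change from IN to IP differed between the sexes for Uty (1.08) and Kdm5d (0.96), Y-linked genes that were near 0 in females.

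In the 8 IN libraries, Scn1a (20.2, low) and Htr1d (15.8, high) in male pool 3 stood apart. In the 8 IP libraries Snurf in male pool 2 (86.2), Th in female pool 3 (32.6) and Ndufa4 in male pool 4 (295) did. Of 156 groups of 8 libraries 23 held such a value, where chance gives 7.8.

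Among the 4 female IN libraries, Ddx3y in pool 1 (0.0438), Pcdha8 in pool 3 (1.69) and Zmym1 in pool 2 (6.98) stood apart. Among the 4 female IP libraries, Xist (11.7), Ptgds (144), Srd5a2 (0.115) and Dopey2 (31.7) did so in pool 2, Gm6222 in pool 3 (9.25), and Ddx3y (0.00257) and Gm12728 (0.571) in pool 4. Among male libraries, Gm527 in IN pool 3 (9.16), Pcdha8 in IN pool 4 (1.39), Gm27640 in IP pool 3 (4.24) and Gm4987 in IP pool 4 (0.763) did. Of 134 groups of 4 libraries 14 held such a value, where chance gives 6.7. These groups share libraries too, so this count is no test of chance either.

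ERCC spike-in entries, which no comparison used, summed to a mean of 1550 TPM in IN and 9590 TPM in IP libraries. In IP the sums ran from 2567 to 7740 TPM in female and from 4521 to 20651 TPM in male libraries. The reason was not tested.

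Counts over other splits of the samples bear on chance. For IP against IN in both sexes, 1 of 100 swaps of IN and IP within pools gave as many as 12783 genes, the real one, so chance can be excluded. The highest other gave 10487, with female pool 2 alone swapped, and swapping male pool 2 alone gave 4898. Such swaps keep the labels of all other pools. The IP libraries of these pools held the highest shares of the IN excess (medians 19.9% and 7.0%). In each sex alone there are 8 swaps, too few for a share under 0.05; the real ones gave 10613 and 11335 genes and the highest other 0. For female against male in IN (13 genes, highest other split 5), in IP (8 and 1) and for the interaction (3 and 2), 1 of 35 splits of the pools gave as many. Genes of the sex chromosomes, 9 and 7 of these calls in IN and IP, set that outcome by themselves. In the interaction the 2 calls of Y-linked genes equal the highest other split without Ep400. These splits therefore say nothing of chance for other genes. For autosomal genes, adjusted without the sex chromosomes, 16 of 35 splits gave as many as the real one in IN (1 gene, Srd5a2, highest other 5) and 3 of 35 in the interaction (1 gene, Ep400, highest other 2), so chance cannot be excluded as the source of these 2 counts. In IP the real split gave 0 autosomal genes and the highest other 1, so that 35 of 35 gave as many by necessity and the count says nothing of chance.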

How the results depend on the processing

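Only the covariate for mitochondrially encoded RNA was chosen after the data were seen. For IP against IN, all 656 values of named genes without 1 pool kept direction and side of the threshold, as did 418 of 422 under other settings. Many of these genes were named for a large change or for the same sign in every pool, which favours that outcome. Under other settings Zfp521 and Nefm lost their calls, and Rplp0 went from -0.42 to 0.01 relative to the median gene of the deposited TPM. Of list calls in both sexes 176 of 176 were kept without 1 pool and 123 of 151 under other settings. For single genes between the sexes, the fits without 1 pool kept 88 of 112 values in IN, 146 of 168 in IP and 108 of 120 in the interaction, and other settings kept 58 of 68, 107 of 123 and 57 of 72.

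Without a filter, more genes were tested and 21019 passed for IP against IN in both sexes and 17144 in males, and 0 in the interaction. Of the genes that passed for IP against IN, 32.8% were higher in the fit of both sexes and 32.8% in males. With the filter these shares were 51.0% and 50.1%. With a minimum of 5 TPM, fewer genes were tested and 8 passed between the sexes in IN. The replicate number does not pair female with male pools, with correlations of -0.299 to 0.101 between libraries of the same number; as a replicate block it left 8 genes in IN and 5 in IP. With mitochondrially encoded RNA as a covariate 5 passed in IP. Without 1 pool the counts were 5 to 12 in IP and 0 to 6 in the interaction. The interaction had 11 genes with deposited TPM, 1 with quantile normalization, and 10 by fold and standardized mean difference.

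Relative to the median gene of the deposited TPM, interaction values turned for Uty (-0.81), Kdm5d (-0.68), Srd5a2 (-0.56), Ddx3y (-1.34, adjusted p = 0.004) and the Y-linked list (-1.07). These genes were near 0 in both female fractions, so the turn follows from the rise of the deposited TPM in male IP. Scn10a in female against male IP, -0.02 and without a call, was 0.05 with quantile normalization, 0.09 with the covariate and -0.10 to 0.12 without 1 pool. Except for the filters and these turned interaction values, the cause was not tested. The depth is unknown, so what it limits was not assessed.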

Other observations

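No test in this part was added after the results were seen, but the genes and lists below were picked for it after their values were seen.

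Atf3, a transcription factor gene induced by nerve injury, was lower in every female library than in every male library of the same fraction. Its level was 2.03 to 2.34 in female and 2.90 to 4.27 in male IN, and 1.38 to 1.62 in female and 2.42 to 4.87 in male IP (4 libraries each). In limma neither difference passed, with adjusted p = 0.63 in IN (log2 -0.49) and adjusted p = 1 in IP (-0.73). Gtpbp4, a gene of ribosome assembly, was at 5.45 to 11.2 in male IP and at 3.20 to 4.38 in female IP, while IN levels were 4.01 to 5.31 in males and 3.74 to 5.12 in females.

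Srd5a2 was near 0 in both female fractions (0.091 in IN and 0.0288 in IP) and at 2.09 and 1.02 in the male fractions. The difference passed in IN (-1.49, adjusted p = 0.0057) and not in IP (-0.95, adjusted p = 0.18), and the interaction did not pass (0.54, adjusted p = 0.56).

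The skeletal muscle list had a median log2 change from IN to IP of -0.17 in female pool 2 and -1.64 in male pool 2, and of -2.30 to -3.48 in the other 6 pools.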
